A study of Mus musculus with 54 samples.

How the data were processed

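RNA of Ba/F3-gp130 cells was measured on 27 Affymetrix mouse arrays. Ba/F3 is a mouse pro-B cell line. The gp130 form carries the signal-transducing chain of the interleukin-6 receptor family and depends on Hyper-IL-6, a fusion of interleukin-6 with its soluble receptor that acts on gp130 directly. Per the labels, 4 lines were used, namely the untransfected (parental) line and the lines CIR-1, CIR-2 and CIR-3, each with a construct of a Cargo Internalization Receptor. Per the labels' protocols, cells were washed 4 times in PBS and kept in serum-free medium for 3 h, and stimulation lasted 1 h, with 50 µl GFP-PFC emulsion per ml or, in parental cells only, with 100 ng/ml Hyper-IL-6 as the positive stimulation control. The 9 groups of line and stimulation held 3 arrays each. The labels name no arm in which emulsion-free liquid was added, and they do not say whether the 3 arrays of a group came from separate cultures. RNA was extracted with RNeasy columns and DNase digestion, amplified with the Ambion WT Expression kit and labelled with biotin, per the labels' protocols.

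Each array was deposited as gene-level and as exon-level values, made by the authors with Affymetrix Expression Console (core-gene and core-exon analysis), per the labels. The algorithm, the program version, the normalization and the log base are not stated. The deposited values were taken as log2 signal because they lay between 2.97 and 14.9 at gene level and between 2.89 and 15.0 at exon level, so fold values rest on that reading. Array medians lay between 7.521 and 7.646 at gene level and between 8.519 and 8.544 at exon level, and the deposited normalization was kept. For 6703 probe sets present in both tables, all 6703 held identical values. The number of arrays per group limits the precision.

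Of 35556 gene-level probe sets, 21789 were listed with 1 gene symbol, 1621 with several symbols and 12146 with none. Where a gene had several probe sets (1015 genes), the probe set with the highest mean over all arrays was used, which gave 19920 genes. No filter on dim probe sets was applied. The Entrez number was found in the mouse gene reference for 21698 probe sets, and 23 symbols were updated to their present form. The exon-level table held 241576 probe sets, of which 212097 carried 1 symbol and covered 20352 genes. Genes are given by symbol, without coordinates, because the tables name no genome build.

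Differences between groups were tested in R 4.3.3 with limma 3.58.1 (with data.table, version 1.17.8, for reading). A linear model with 1 mean per group was fitted to all 27 arrays, and moderated tests were two-sided, with Benjamini-Hochberg adjustment over the 19920 genes and a threshold of 0.05. All adjusted p values of genes come from this fit unless another setting is named, and every SE is the standard error of the fitted difference. GFP-PFC was compared with no stimulation in each line and as the mean difference over the 4 lines, and moderated F-tests asked whether that difference varied among the lines and whether the 3 CIR lines differed from each other. Gene lists on signalling, stress, lipid handling, endocytosis, the cell cycle and blood cell types, 28 in all, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison. Camera compares a list with all other genes. The lists share some members, and genes that are not analysed here were left out of them. The comparisons, the lists, the alternatives and the rule for named genes were set before the data were examined, except where the text says otherwise.

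By the rule for named genes, each comparison could name the 10 highest rises and the 10 largest falls among genes under the threshold whose 3 values in one group all lay above the 3 of the other. For the mean of 4 lines, the same sign in each line was asked instead. Chance alone gives non-overlapping groups of 3 and 3 for 10% of unchanged genes. The rule added Socs3 in every stimulation comparison, up to 4 passing members of each list that was called or held at least 2 passing members, every passing gene of the receptor list in the line comparisons, and the 5 genes with the smallest p where fewer than 3 genes passed. The text may name fewer, in that order.

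Replicate numbers in the labels were 1, 3 and 5 for unstimulated and 2, 4 and 6 for stimulated arrays. Lines under the same stimulation share these numbers, and consecutive numbers within a line were taken as an assumed pairing that the labels do not state. Deviations from the group means were positively correlated between all 12 consecutive pairs of the same line (r across genes 0.283 to 0.633), between all 18 same-numbered unstimulated pairs (0.136 to 0.763) and between all 9 pairs of a parental and a CIR GFP-PFC array with the same number (0.224 to 0.615). The numbers were treated as pairing the unstimulated and GFP-PFC arrays. A fit with a block of 3 levels (numbers 1 and 2, 3 and 4, 5 and 6) was run as the paired alternative. Correlations between unmatched numbers were not computed. Since the arrays numbered 1 and 2 deviated together, the correlations cannot tell pairs 3 and 4, 5 and 6 from pairs 3 and 6, 5 and 4.

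The procedure was tested on simulated data with 200 changed genes. A change of 0.5 on the log2 scale was recovered for 68.7% to 76.1% of the genes given it in the comparison of Hyper-IL-6 with no stimulation, for 74.6% to 80.6% in that of CIR-1 with parental cells and for 100% in the mean of 4 lines, without the block in the fit. A difference of 1 in the GFP-PFC effect, given to CIR-3 alone, was recovered by the F-test for 95% of 200 genes drawn at random, with independent noise. Genes with a wide spread, such as Dusp6 (SE 0.32 in each line), were not examined apart, and smaller differences were not simulated for this test. A list shifted by 0.3 was called, with 0 other calls among the 28 lists. The noise in that simulation was independent between genes, so it does not show how often camera calls unshifted lists of correlated genes. Alternatives were quantile normalization or median centring on top of the deposited values, leaving out genes below the median level, a fit to the compared groups alone, the replicate block, array weights, a trended robust variance prior, every probe set on its own, the median of a gene's exon-level values, each array left out in turn, an estimated inter-gene correlation and, for lines, GFP-PFC arrays or the mean over both conditions. After the data were seen, 2 more were added, which left out the arrays numbered 1 and 2 or ran the block without the Hyper-IL-6 arrays. Other splits of the arrays were drawn up to 100 times, and unchanged groups were simulated 50 times for the overlap of calls.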

Results

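Gene expression was measured in Ba/F3-gp130 cells on 27 arrays, 3 in each of 9 groups. Parental cells and the lines CIR-1, CIR-2 and CIR-3 were each measured unstimulated and after 1 h with GFP-PFC, a perfluorocarbon (PFC) emulsion whose name in the labels includes green fluorescent protein (GFP). Parental cells were also measured after 1 h with Hyper-IL-6. The stated purpose was to see the overall influence of the receptor constructs on the cells. Values are log2 signals of 19920 genes, differences are on the log2 scale, and n = 3 arrays per group unless another number is given. Array medians ranged from 7.521 to 7.646. Means below the lower quartiles of the arrays (6.218 to 6.311) were not shown to lie above background, so differences and folds against them are ratios of signals and lower bounds on the change in RNA. Correlations between arrays of the same group ran from 0.9925 to 0.9988 and between groups from 0.9913 to 0.999, both across genes. Arrays numbered 1 and 2 deviated from their group means in the same direction along the first component of all deviations (42.4% of their variance) in all 8 groups without Hyper-IL-6, and Hyper-IL-6 array 2 deviated the other way.

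Genes of the gp130/STAT3, STAT5, MAPK, ERK feedback and NF-kB lists rose after Hyper-IL-6 in parental cells, the comparison with a known gp130 ligand. The labels name no arm with an addition free of ligand, so a part due to handling or fresh medium was not separated. The cytokines Osm and Lif rose by 3.77 (SE 0.22, 13.6-fold) and 3.73 (SE 0.28, 13.3-fold). Socs3, the feedback inhibitor of gp130 signalling (probe set 10393449), rose from 9.784 ± 0.26 to 12.84 ± 0.26 (mean ± SD, n = 3), an 8.33-fold increase (adjusted p = 2.14e-07). The stress-response gene Gadd45g rose by 3.12 (SE 0.14), the mRNA decay factor Zfp36 by 2.97 (SE 0.28), the cytokine Il10 by 2.85 (SE 0.28) the early response gene Ier3 by 2.73 (SE 0.32) and the receptor gene Gpr146 by 2.34 (SE 0.15). In limma, 154 genes passed, 146 higher and 8 lower, and 49 of them rose by 1 or more while 0 fell by as much. The largest fall was that of the lectin gene Clec2d, by 0.89 (SE 0.14, adjusted p = 0.000898).

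Of 20 measured gp130/STAT3 early targets, 14 rose, 0 fell and the others did not pass (16 rose adjusted over the list alone, adjusted p = 3.64e-48). Among them Junb rose by 1.46 (SE 0.12), the transcription factor Irf1 by 1.52 (SE 0.13) and the SOCS family member Cish by 2.07 (SE 0.19). Of 11 STAT5 targets, 5 rose (7 adjusted over the list alone, adjusted p = 9.12e-18), including the differentiation inhibitor Id1 by 1.47 (SE 0.24). Of 21 MAPK immediate early genes, 12 rose (15 adjusted over the list alone, adjusted p = 2.97e-35), including Gadd45b by 1.14 (SE 0.12). ERK feedback genes, which encode phosphatases and Sprouty proteins that dampen the pathway, had 5 of 12 members that rose (7 adjusted over the list alone, adjusted p = 8.05e-15), among them Dusp2 by 0.74 (SE 0.14), Spry2 by 0.94 (SE 0.18) and Dusp6 by 1.44 (SE 0.32). Of 20 NF-kB and inflammatory genes, 6 rose (9 adjusted over the list alone, adjusted p = 5.54e-18), such as Il6 by 1.89 (SE 0.23) and the chemokine Ccl4 by 0.62 (SE 0.11). Hypoxia genes rose as a list (adjusted p = 0.00152), with 2 of 22 members passing, the glycolytic enzyme Hk2 (0.99, SE 0.16) and the growth factor Vegfa (0.51, SE 0.11). These 6 lists were also called with an estimated correlation, at adjusted p values from 0.000143 to 0.0115. Apoptosis regulators (adjusted p = 0.00168), oxidative stress genes (adjusted p = 0.0111) and unfolded protein response genes (adjusted p = 0.0498) were called upward only with the preset correlation (adjusted p = 0.071, 0.652 and 0.652 with an estimated correlation), and 1 of 13, 0 of 14 and 0 of 17 of their members rose.

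The count was 96 without unstimulated array 3, 248, 78 and 79 without Hyper-IL-6 arrays 2, 4 and 6, 31 in a fit to the 6 compared arrays alone, where the calls of Il10, Il6, Ccl4, Dusp2, Hk2 and Clec2d ended, and 3673 without the arrays numbered 1 and 2, where most calls were lower (1362 higher, 2311 lower), as with array weights (1358 higher, 2110 lower). On the first component of the deviations, Hyper-IL-6 arrays 4 and 6 lay at −2.22 and −5.36, and parental unstimulated arrays 3 and 5 at 11.8 and 12.1. Leaving out numbers 1 and 2 thus moved both group means along this component, in opposite directions. Deviations are taken from each group's own mean, so they do not show where the groups lay relative to each other. Whether this setting removed the array structure or added it to the comparison was not tested. The survival kinase gene Pim1 rose by 2.28 (SE 0.53, adjusted p = 0.0388), but it did not pass once any of the 6 arrays was left out. Leaving out 1 array also ended the calls of Dusp2, Spry2, Dusp6, Vegfa and all falls except that of Clec2d, and exon-level values ended those of Pim1, Spry2, Dusp6, Ccl4 and Hk2.

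**Figure D1:**
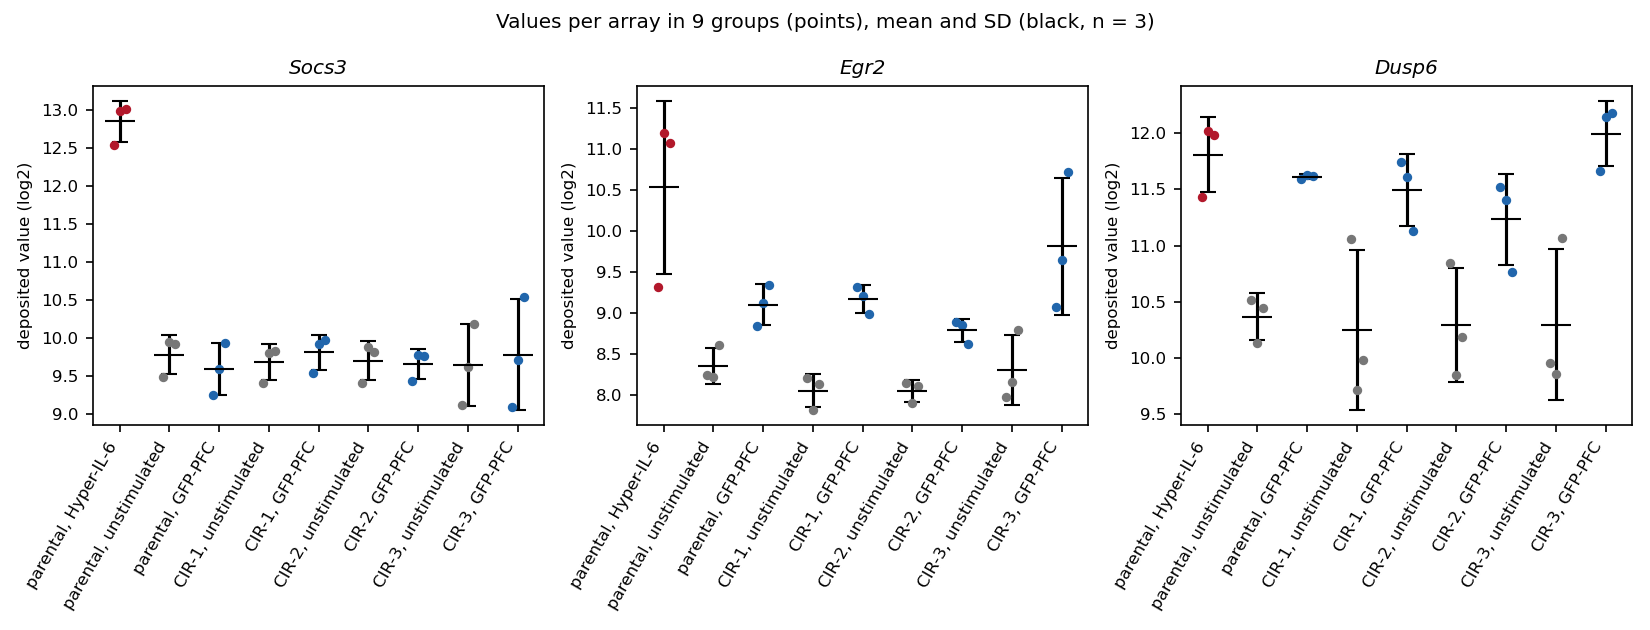
Log2 signal of Socs3, Egr2 and Dusp6 on the vertical axis for each array in the 9 groups on the horizontal axis, with points for arrays and the mean and SD of 3 arrays per group. Socs3 stood at 12.84 after Hyper-IL-6 and at 9.596 after GFP-PFC in parental cells.

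GFP-PFC was compared with no stimulation to see whether cells respond to the emulsion, averaged over the 4 lines (12 arrays against 12). Genes of the ERK pathway rose. The ERK phosphatase Dusp6 (probe set 10366043) rose by 1.28 (SE 0.16, 2.43-fold, adjusted p = 0.000392), and the related phosphatases Dusp5 and Dusp4 rose by 1.01 (SE 0.15) and 0.74 (SE 0.11). The immediate early transcription factors Egr2 and Fosl1 rose by 1.03 (SE 0.18) and 0.76 (SE 0.11), the kinase Plk3 by 1.03 (SE 0.19), Il6 by 0.64 (SE 0.12), and Myc by 0.58 (SE 0.10). Each of these genes was higher in 12 of 12 pairs of consecutive arrays. Of 7 genes that fell, Rnf145, a ubiquitin ligase gene, had the largest fall, by 0.50 (SE 0.052, adjusted p = 3.79e-05, higher in 0 of 12 pairs), the zinc finger gene Zkscan14 fell by 0.32 (SE 0.053) and the glucocorticoid-induced gene Tsc22d3 fell by 0.29 (SE 0.053). Socs3 differed by 0.01 (SE 0.14, adjusted p = 0.999, higher in 7 of 12 pairs).

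Of 21 MAPK immediate early genes, 4 rose (14 adjusted over the list alone, adjusted p = 1.78e-27), namely Fosl1, Egr2, Ier2 and Myc. Of 12 ERK feedback genes, 3 rose (9 adjusted over the list alone, adjusted p = 1.62e-16), namely Dusp6, Dusp5 and Dusp4. Both lists were also called with an estimated correlation (adjusted p = 0.00345 for each). NF-kB and inflammatory genes (adjusted p = 2.26e-05, 1 of 20 rose, 3 adjusted over the list alone), STAT5 targets (adjusted p = 0.000173, 0 of 11 rose, 3 adjusted over the list alone) and cholesterol synthesis genes (adjusted p = 0.00905, 0 of 18 rose, 1 adjusted over the list alone) were called upward with the preset correlation, and each had an adjusted p = 0.274 with an estimated correlation. The same held for gp130/STAT3 early targets (adjusted p = 0.000358, 1 of 20 rose, 2 rose and 1 fell adjusted over the list alone), with an adjusted p = 0.466 with an estimated correlation, and for ribosome biogenesis genes (adjusted p = 0.00808, 0 of 22 rose), with 0.47. Amino acid response genes were called upward and T-cell markers downward (adjusted p = 0.021 for each, 0 members passing), both with an adjusted p = 0.656 with an estimated correlation. Clathrin endocytosis genes (23 measured, adjusted p = 0.655) and lysosome genes (25 measured, adjusted p = 0.506) were not called, and 0 of their members passed. The median of the lysosome genes was −0.0063 and their mean 0.0069.

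In this mean of 4 lines 44 genes passed, 37 higher and 7 lower. With the replicate block the count was 151 (262 without the Hyper-IL-6 arrays), without the arrays numbered 1 and 2 it was 944 (331 higher, 613 lower), with array weights it was 1071 (409 higher, 662 lower), without parental unstimulated array 1 it was 71, and with exon-level values it was 25, where the calls of Fosl1, Myc and Tsc22d3 ended. The call of Plk3 ended when every probe set was tested on its own. Of the 37 higher genes, 10 were also called higher after Hyper-IL-6, against 0.27 for independent lists, in comparisons that share the 3 unstimulated parental arrays. In the mean of the 3 CIR lines, which shares no array with the Hyper-IL-6 comparison, it was 5 of 13, against 0.095.

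Within single lines, 3 arrays against 3, limma called 0 genes after GFP-PFC in each of the 4 lines. At an unadjusted p under 0.05 there were 781 genes in parental cells, 489 in CIR-1, 264 in CIR-2 and 427 in CIR-3, and the smallest adjusted p values were 0.485, 0.202, 0.303 and 0.209. The difference of Dusp6 was 1.25 in parental cells, 1.24 in CIR-1, 0.94 in CIR-2 and 1.69 in CIR-3 (SE 0.32 each), and that of Rnf145 was −0.48, −0.46, −0.57 and −0.48 (SE 0.10 each). MAPK immediate early genes were called as a list in each line, with adjusted p = 3.5e-09, 2.76e-15, 4.91e-10 and 3.1e-25 in the same order (adjusted p = 0.242, 0.0461, 0.349 and 0.00752 with an estimated correlation). ERK feedback genes had adjusted p = 1.22e-07, 2.54e-10, 6.4e-05 and 5.12e-14 (adjusted p = 0.184, 0.0461, 0.349 and 0.00752 with an estimated correlation). With the replicate block the counts were 0 in parental cells, 1 in CIR-1, 1 in CIR-2 and 10 in CIR-3, and in that block without the Hyper-IL-6 arrays they were 1, 0, 1 and 19. The count in parental cells was 1010 with array weights (291 higher, 719 lower), 88 without the arrays numbered 1 and 2 (31 higher, 57 lower, a setting chosen after the data were seen) and 7 without parental unstimulated array 1. Without the arrays numbered 1 and 2 the count in CIR-3 was 4, and without CIR-3 unstimulated array 5 that in CIR-3 was 2.

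Whether the constructs changed the response to GFP-PFC was asked by an F-test of its difference among the 4 lines. In limma 0 genes passed (187 at an unadjusted p under 0.05, with 0 also in the fits with the block). The smallest adjusted p was 0.0968, for Gm4907, and those of Dusp6, Egr2, Dusp5, Fosl1 and Rnf145 were 1. Against parental cells, each single CIR line also had 0 passing genes, with 245, 251 and 348 at an unadjusted p under 0.05 for CIR-1, CIR-2 and CIR-3. A count of 0 does not show equal responses, since differences smaller than 1 were not simulated for the F-test.

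**Figure D2:**
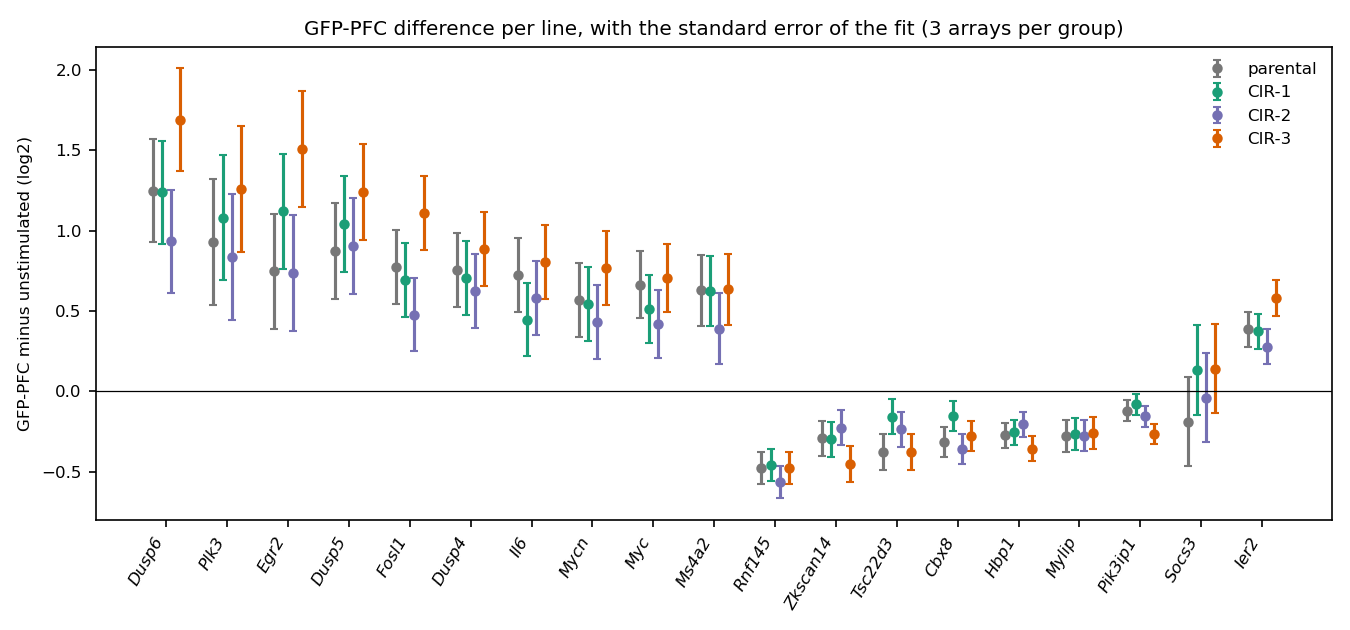
Log2 difference between GFP-PFC and unstimulated arrays on one axis for 19 genes on the other, with 1 point per line (parental, CIR-1, CIR-2, CIR-3) and bars for the SE of the fit. Dusp6 lay between 0.935 and 1.69 in the 4 lines, and Rnf145 between −0.567 and −0.461.

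Hyper-IL-6 and GFP-PFC were then compared directly in parental cells. Socs3 was 9.49-fold higher after Hyper-IL-6 (3.25, SE 0.28, adjusted p = 8.49e-08), Osm was higher by 3.33 (SE 0.22), Lif by 3.29 (SE 0.28) and Gadd45g by 3.06 (SE 0.14). Of 20 gp130/STAT3 early targets, 13 were called higher after Hyper-IL-6 (adjusted p = 7.96e-43, adjusted p = 0.000301 with an estimated correlation), such as Irf1 by 1.87 (SE 0.13). Of 21 MAPK immediate early genes, 7 were higher (adjusted p = 3.93e-18, adjusted p = 0.0155 with an estimated correlation). ERK feedback genes differed as a list (adjusted p = 0.000529) with 0 of 12 members passing, 4 adjusted over the list alone, and an adjusted p = 0.207 with an estimated correlation. How much of their rise after Hyper-IL-6 was specific to this ligand therefore stayed open. STAT5 targets (3 of 11 higher, adjusted p = 3.27e-13), NF-kB and inflammatory genes (4 of 20, 4.84e-12) and hypoxia genes (1 of 22, 0.00126) were also called higher, with adjusted p = 0.0112, 0.0247 and 0.0155 with an estimated correlation, as were apoptosis regulators (1 of 13, adjusted p = 0.0031), with adjusted p = 0.107 with an estimated correlation. Called lower after Hyper-IL-6 were cholesterol synthesis genes (adjusted p = 0.02), G2/M genes (adjusted p = 0.0449) and ribosome biogenesis genes (adjusted p = 0.019), with 0 members passing in each and adjusted p = 0.236, 0.603 and 0.46 with an estimated correlation. In limma 101 genes passed, 98 higher and 3 lower. The count was 66 in a fit to the compared arrays alone, 236 without the arrays numbered 1 and 2 (191 higher, 45 lower), 1927 with array weights (963 higher, 964 lower), 55 and 57 without GFP-PFC arrays 2 and 4, and 155, 40 and 42 without Hyper-IL-6 arrays 2, 4 and 6.

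CIR-1 cells were compared with parental cells, both unstimulated, for the influence of the construct at rest. Fcer1a, the alpha chain of the high-affinity IgE receptor (probe set 10360338), fell from 9.094 ± 0.92 to 4.99 ± 0.23 (mean ± SD, n = 3), a 17.2-fold lower signal and a lower bound (adjusted p = 1.64e-09). The myeloid lectin Clec12a fell by 2.99 (SE 0.34), the lipid transporter gene Atp8b4 by 2.84 (SE 0.24), the fatty acyl reductase Far2 by 2.57 (SE 0.11), and Gask1b fell by 2.64 (SE 0.11). The urea transporter Slc14a1 rose by 2.83 (SE 0.19, 7.11-fold), 3830403N18Rik by 2.23 (SE 0.19), galectin-3 (Lgals3) by 1.94 (SE 0.099), the retinal dehydrogenase Aldh1a1 by 1.88 (SE 0.24), the iron-siderophore binding lipocalin Lcn2 by 1.84 (SE 0.22) and coagulation factor F5 by 1.79 (SE 0.17). Of 10 erythroid and megakaryocyte markers, 4 rose (4 adjusted over the list alone, adjusted p = 9.37e-05, adjusted p = 0.0241 with an estimated correlation), namely the transcription factors Gata1 (0.43, SE 0.066) and Klf1 (0.68, SE 0.13), the erythropoietin receptor Epor (0.37, SE 0.065) and the integrin Itga2b (0.33, SE 0.075). Ribosome biogenesis genes were called downward with 0 of 22 members passing (adjusted p = 9.37e-05, adjusted p = 0.515 with an estimated correlation), as were G1/S genes with 0 of 22 (adjusted p = 0.0147, adjusted p = 0.721 with an estimated correlation). In limma 344 genes passed, 227 higher and 117 lower. The count was 701 with the block (962 without the Hyper-IL-6 arrays), 56 in a fit to the compared arrays alone and 216 with exon-level values. The calls of Gata1, Klf1, Epor and Itga2b ended in the fit to the compared arrays alone, those of Epor and Itga2b also with exon-level values, and that of Itga2b when 1 array was left out.

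In CIR-2 cells, compared with parental cells in the same way, 2 genes rose by more than 4. The 3830403N18Rik gene rose by 4.93 (SE 0.19, 30.5-fold, adjusted p = 1.21e-14) and Xlr, an X-linked lymphocyte-regulated gene, by 4.48 (SE 0.18, 22.3-fold), both lower bounds. The aldo-keto reductase Akr1b8 rose by 2.69 (SE 0.17), the phospholipase Plcb4 by 2.53 (SE 0.16), the kinase Hipk2 by 2.40 (SE 0.11), and the heparan sulfate sulfotransferase Hs3st1 by 2.39 (SE 0.091). Fcer1a fell by 4.06 (SE 0.28, 16.7-fold), Atp8b4 by 2.72 (SE 0.24) and Gask1b by 2.38 (SE 0.11), the actin-severing protein Scin fell by 2.30 (SE 0.24), and granzyme B (Gzmb) fell by 1.85 (SE 0.21). Of 10 erythroid and megakaryocyte markers, 1 rose, Epor by 0.45 (SE 0.065), and 4 rose adjusted over the list alone (adjusted p = 0.000468, adjusted p = 0.0484 with an estimated correlation). G1/S genes were called downward with 0 of 22 members passing (adjusted p = 0.000195, adjusted p = 0.537 with an estimated correlation). Mast cell and basophil markers were called downward (adjusted p = 0.00864, adjusted p = 0.339 with an estimated correlation), where 1 of 13 fell, Fcer1a, and 1 rose and 4 fell adjusted over the list alone. STAT5 targets were called upward (adjusted p = 0.0224, adjusted p = 0.947 with an estimated correlation), where 1 of 11 rose, the survival gene Bcl2l1 by 0.49 (SE 0.12), a call that ended when 1 array was left out. In limma 240 genes passed, 176 higher and 64 lower. The count was 492 with the block (674 without the Hyper-IL-6 arrays), 70 in a fit to the compared arrays alone, 621 without the arrays numbered 1 and 2, and 137 and 152 without CIR-2 unstimulated arrays 3 and 5. The calls of Epor and Bcl2l1 ended in the fit to the compared arrays alone, and that of Epor also with exon-level values.

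CIR-3 cells were compared with parental cells in the same way. The Gm773 gene (probe set 10604674) rose from 4.61 ± 0.17 to 10.02 ± 0.35 (mean ± SD, n = 3), a 42.4-fold increase in signal and a lower bound (adjusted p = 9.62e-19), while it stood at 4.863 in CIR-1 and 4.887 in CIR-2. Lgals3 rose by 3.98 (SE 0.099, 15.8-fold), the piRNA-pathway helicase Tdrd9 by 3.79 (SE 0.14), annexin A3 (Anxa3) by 3.61 (SE 0.19) and the meiosis gene M1ap by 3.28 (SE 0.22). Fcer1a fell by 4.09 (SE 0.28), the lectin Clec4e by 1.71 (SE 0.25), Mettl7b by 1.58 (SE 0.17) and the beta-secretase Bace1 by 1.40 (SE 0.079). All 17 unfolded protein response genes had positive differences (mean 0.16), and 0 of them passed; the list was called upward (adjusted p = 6.21e-08, adjusted p = 0.305 with an estimated correlation). Lysosome genes were called upward (adjusted p = 0.023, adjusted p = 0.429 with an estimated correlation), where 1 of 25 rose, the sialidase Neu1 by 0.49 (SE 0.092), and 1 fell, the protease Ctss by 0.45 (SE 0.10). Mast cell and basophil markers were called downward (adjusted p = 0.027, adjusted p = 0.305 with an estimated correlation), where 1 of 13 fell, Fcer1a, and 2 rose and 3 fell adjusted over the list alone. In limma 297 genes passed, 238 higher and 59 lower, and with median centring 362 were higher and 38 lower. The count was 658 with the block (1102 without the Hyper-IL-6 arrays), 79 in a fit to the compared arrays alone, 3233 without the arrays numbered 1 and 2 (1331 higher, 1902 lower), 3803 with array weights (1534 higher, 2269 lower), 190 without parental array 3, 187 without CIR-3 array 3, and 1642 without parental array 1, of which 709 were higher and 933 lower. The call of Ctss ended when 1 array was left out, and those of Neu1 and Ctss with exon-level values.

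**Figure D3:**
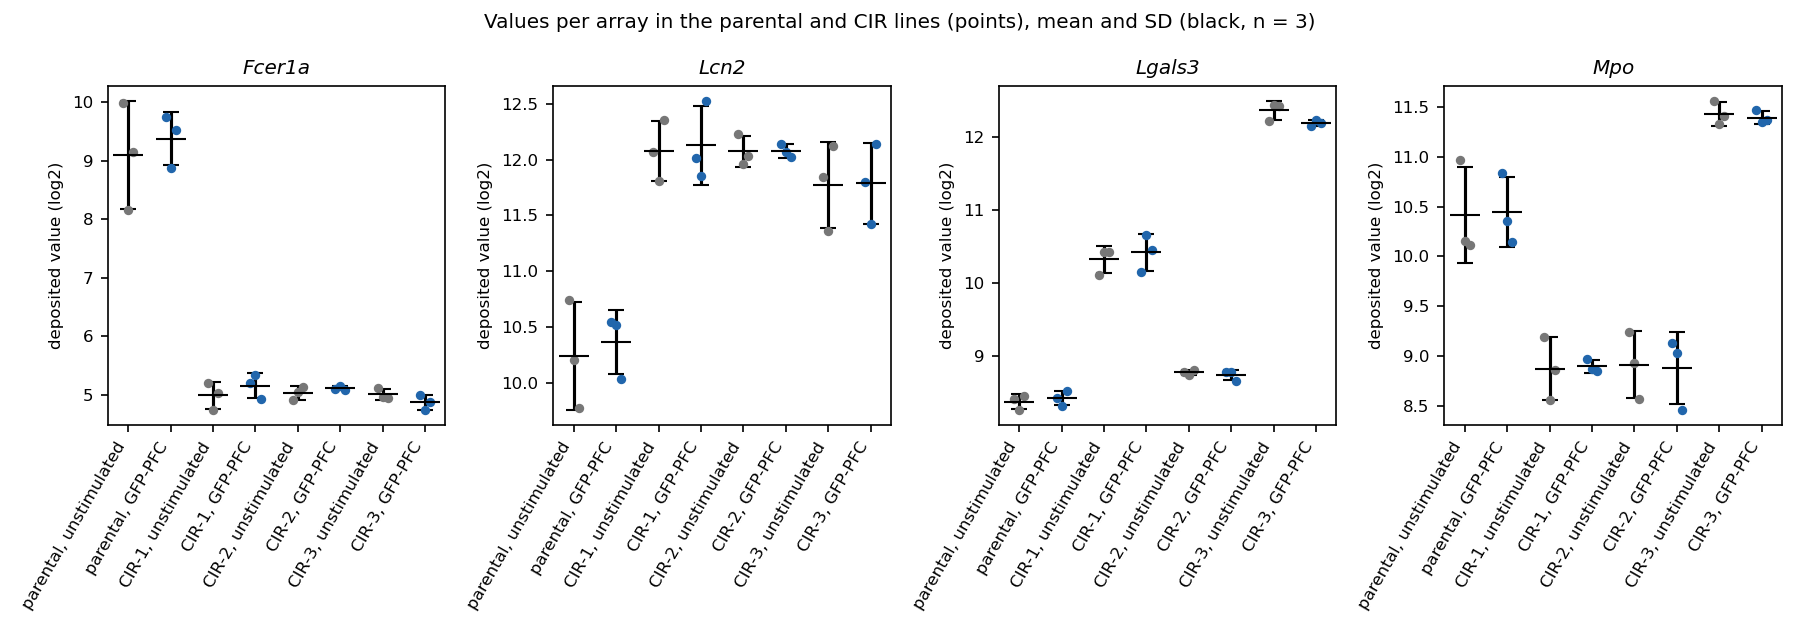
Log2 signal of Fcer1a, Lcn2, Lgals3 and Mpo on the vertical axis for each array of the 4 lines, unstimulated and after GFP-PFC, with points for arrays and the mean and SD of 3 arrays per group. Unstimulated Fcer1a averaged 9.094 in parental cells and between 4.99 and 5.031 in the CIR lines.

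The 3 CIR lines also differed from each other. Gm773 was highest in CIR-3 (F-test adjusted p = 1.39e-18), Xlr and 3830403N18Rik in CIR-2 (1.21e-13 and 3.16e-12), Clec12a was lowest in CIR-1 (4.06e-07), and Lgals3, Tdrd9 and Anxa3 were highest in CIR-3 (4.37e-17, 4.83e-15 and 1.63e-10). In limma's F-test 287 genes passed, with 83 genes between CIR-2 and CIR-1, 236 between CIR-3 and CIR-1 and 152 between CIR-3 and CIR-2. The count was 510 with the block, 675 in that block without the Hyper-IL-6 arrays, 139 in a fit to the 9 compared arrays alone and 442 without the arrays numbered 1 and 2. Each CIR construct was present in 1 line, so the construct and the line it sits in cannot be told apart.

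A set of genes was called in the same direction against parental cells in all 3 CIR lines, 71 higher and 17 lower. Lcn2 rose by 1.84, 1.83 and 1.53 in CIR-1, CIR-2 and CIR-3 (SE 0.22 each), and Lgals3 by 1.94, 0.40 and 3.98 (SE 0.099 each). Among the genes that fell in all 3 were Fcer1a, Clec4e, Mettl7b and C1ra. Unchanged groups and shared parental arrays, both simulated around the parental means with independent noise, gave 0 such genes in 50 simulations. Unchanged groups give few calls in any line, so this 0 was near certain beforehand. It does not show how far lists of the real length overlap through shared controls. Independent lists would give 0.024 higher and 0.0011 lower. Correlations of the log2 differences across genes, which are not independent replicates, were 0.694 (CIR-1 and CIR-2), 0.525 (CIR-1 and CIR-3) and 0.552 (CIR-2 and CIR-3), against 0.5 simulated. Their covariances were 0.0169, 0.0143 and 0.015, against 0.00609, 0.00608 and 0.00609 simulated. With unstimulated arrays for one line and GFP-PFC arrays for the other, so that no array was shared, the covariances were 0.014, 0.0106 and 0.0111. Genes called higher in both lines of these pairs numbered 95, 84 and 83 without a shared array, against 108, 104 and 100 with shared arrays. Independent lists would give 2, 2.2 and 1.7 without a shared array. Genes called lower numbered 35, 28 and 23, against 37, 27 and 25. Most of the excess in pairs of lines thus remained without shared arrays. The parental unstimulated and GFP-PFC arrays come from the same line, however, and their deviations correlated between consecutive numbers (r 0.615, 0.346 and 0.578). Noise common to these pairs was not removed, so the check does not show an excess free of the parental controls. The 3 parental arrays cannot be split into parts of at least 2, so part of the excess of calls in all 3 lines may come from the shared controls. The labels name no line transfected without a CIR construct, so what the 3 lines share cannot be tied to the constructs.

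Of 26 measured receptor genes whose parts a construct could hold, Epor rose in each CIR line, by 0.37, 0.45 and 0.29 (SE 0.065), and the IgG receptor Fcgr1 rose in CIR-1 by 0.73 (SE 0.13), while 0 fell. With exon-level values the Epor calls in all 3 lines and the Fcgr1 call ended, and the CIR-3 call of Epor also ended when 1 array was left out. The gp130 gene Il6st differed by 0.03, 0.02 and −0.04 in CIR-1, CIR-2 and CIR-3, and it did not pass in any of them. It stood at 6.332 in parental cells, close to the lower quartiles of the arrays (6.218 to 6.311). Its signal therefore does not show whether gp130 RNA was unchanged. Other members of the list, such as Cd36 at 4.599, lay lower still.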

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

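Among the results and tests in this part, the contrast for Gm4907, the test of uptake through the CIR constructs, the tests without the arrays numbered 1 and 2, the block without the Hyper-IL-6 arrays, and the tests of the shared parental arrays and of mast cells were chosen after the result was seen. Genes that passed against parental cells in opposite directions in 2 CIR lines, and also differed between those lines, were singled out. In CIR-1 and CIR-2 this was 1 gene, the immunoglobulin superfamily member Igsf6 (−1.20 and 1.66, difference 2.86, SE 0.28, adjusted p = 1.1e-06). In CIR-1 and CIR-3 there were 3, Mpo (−1.55 and 1.02, difference 2.56, SE 0.21, adjusted p = 2e-08), Myct1 (1.24 and −1.17) and Tent5a (−0.42 and 0.86). In CIR-2 and CIR-3 there were 2, Mpo (−1.51 and 1.02) and Slc24a5 (0.53 and −1.14). Mpo encodes the myeloperoxidase of neutrophil granules, and its rise in CIR-3 no longer passed when 1 array was left out or with exon-level values.

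Gm4907 stood out because its difference after GFP-PFC was positive in the CIR lines and negative in parental cells. Its difference after GFP-PFC was −0.35 in parental cells and 0.63, 0.46 and 0.62 in CIR-1, CIR-2 and CIR-3 (SE 0.11 each). The mean over the 3 CIR lines minus the parental difference was 0.916 (SE 0.13, adjusted p = 0.00713), the 1 gene of 19920 to pass in that contrast, but this contrast was formed after the gene had been seen to have the smallest p of the planned F-test over the 4 lines. That test had an adjusted p = 0.0968, 0.124 with the block and 0.407 in the block without the Hyper-IL-6 arrays, and it passed with median centring (adjusted p = 0.0458) and with array weights (adjusted p = 0.0165) but in no other setting run (adjusted p = 0.0607 to 1), so the call depends on the setting. The exon-level median over 2 probe sets gave −0.146, 0.633, 0.456 and 0.505. Within single lines this gene passed in CIR-3 with the block (adjusted p = 0.0339) and in the block without the Hyper-IL-6 arrays (adjusted p = 0.0447), and in CIR-1 with median centring (adjusted p = 0.0441), but in no line without these settings.

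Probe sets listed without a gene, 12146 in number and outside the comparisons above, were tested in the same limma fit. Of them 2 passed after Hyper-IL-6 (both higher), 15 in CIR-1 (6 higher, 9 lower), 9 in CIR-2 (4 higher, 5 lower), 7 in CIR-3 (4 higher, 3 lower), 10 among the CIR lines and 2 between Hyper-IL-6 and GFP-PFC (both higher).

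ERK-pathway genes rose after GFP-PFC in the mean of 4 lines. Uptake through the CIR constructs as the whole cause was argued against by parental cells, where the 13 genes called in the CIR mean had a median difference of 0.397 (quartiles 0.24 to 0.757, 12 of 13 positive) against 0.455 in the CIR lines. A brightness or normalization trend shared by genes of similar level was argued against by 720 uncalled genes matched on level. Their median was 0.0086 (quartiles −0.019 to 0.038), against 0.33 for the called genes, which were picked for being higher. The arrays numbered 1 and 2 were argued against as the source, because the 33 members of the MAPK and ERK lists had a mean of 0.368 without them (0.355 with all arrays). A response to the emulsion may remain as a hypothesis, and so may one to handling or fresh medium, which was not tested because the labels name no arm with an addition free of emulsion.

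Fcer1a was lower by more than 4 in all 3 CIR lines, and chance values of the shared unstimulated parental arrays were argued against by the GFP-PFC arrays, which share none of them and where the smallest fall was −4.22. Those arrays were taken as paired with the unstimulated ones, so noise common to a pair was not removed. Mast cells mixed into the parental line would raise the other 12 measured mast cell and basophil markers there too, which was argued against by their lowest median difference among the lines, −0.18 (SE 0.076, CIR-3), with 0.30, 0.37 and 0.59 for Ms4a2 (7.80 in parental cells), 0.25, 0.26 and 0.25 for Gata2 (13.08) and −0.24, −0.29 and −0.28 for Cpa3 (5.73). Against this, Hdc (8.32) differed by −0.80, −0.82 and −0.42 (SE 0.22 each) without passing, and the list, Fcer1a included, was called downward in CIR-2 and CIR-3 (adjusted p = 0.00864 and 0.027, adjusted p = 0.339 and 0.305 with an estimated correlation). A single faulty probe was argued against by 4 of 5 exon-level probe sets of the gene, which were lower by 1 or more in all 3 lines. The constructs, or a parental culture that differs from the cells the lines were made from, could each give such a fall. They were not tested, since all 3 lines were compared with the same 1 parental line and the labels name no line transfected without a CIR construct.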

How the results depend on the processing

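Of the alternatives in this part, leaving out the arrays numbered 1 and 2 and the block without the Hyper-IL-6 arrays were chosen after the data were seen. Numbers below are counts of passing genes, and the cause of a move was not tested unless it is named. In the comparison of Hyper-IL-6 with no stimulation (154), the count was 31 with the compared groups alone, 3468 with array weights, 92 with exon-level medians, 3673 without the arrays numbered 1 and 2, and 78 to 248 with 1 array left out. For Hyper-IL-6 against GFP-PFC (101), the same settings gave 66, 1927, 65, 236 and 40 to 155. For GFP-PFC in parental cells (0), array weights gave 1010 (291 higher, 719 lower), leaving out the arrays numbered 1 and 2 gave 88 (31 higher, 57 lower), and leaving out 1 array gave 0 to 7. For GFP-PFC in CIR-1 (0), median centring and exon-level medians gave 1 each, and in CIR-2 (0) array weights gave 1. For GFP-PFC in CIR-3 (0), array weights and exon-level medians gave 1 each, leaving out the arrays numbered 1 and 2 gave 4, and leaving out 1 array gave 0 to 2. For the mean of 4 lines (44), the counts were 1071 with array weights, 25 with exon-level medians, 944 without the arrays numbered 1 and 2, and 34 to 71 with 1 array left out. For the difference of the GFP-PFC effect among lines (0), median centring and array weights gave 1 each, Gm4907 in both. For CIR-1 (344), the counts were 56 with the compared groups alone, 575 with array weights, 216 with exon-level medians and 979 for the mean over unstimulated and GFP-PFC arrays. For CIR-2 (240), they were 70, 940 with array weights, 757 for that mean, 621 without the arrays numbered 1 and 2, and 137 to 319 with 1 array left out. For CIR-3 (297), they were 79 with the compared groups alone, 3803 with array weights, 191 with exon-level medians, 837 for that mean, 3233 without the arrays numbered 1 and 2, and 187 to 1642 with 1 array left out. Among the CIR lines (287), they were 139 with the compared groups alone, 991 with array weights, 180 with exon-level medians and 442 without the arrays numbered 1 and 2. A fit to the compared groups alone has fewer arrays for the spread, and the mean over both conditions has more. Genes called in the same direction in all 3 CIR lines numbered 47 at an adjusted p under 0.01 (88 at the main threshold), and 80 in the GFP-PFC arrays. Of 280 list tests, 58 were called, 19 of them also with an estimated correlation. With dim genes left out, 46 of 250 list tests were called, of which 37 were among the 58.

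With the replicate block, counts were 325 for Hyper-IL-6, 251 for Hyper-IL-6 against GFP-PFC, 1 for GFP-PFC in CIR-1, 1 in CIR-2, 10 in CIR-3, 151 in the mean of 4 lines, 701 for CIR-1, 492 for CIR-2, 658 for CIR-3 and 510 among the CIR lines. In the block without the Hyper-IL-6 arrays they were 1 for GFP-PFC in parental cells, 1 in CIR-2, 19 in CIR-3, 262 in the mean of 4 lines, 962 for CIR-1, 674 for CIR-2, 1102 for CIR-3 and 675 among the CIR lines. Every gene called without the block was also called with it. Of the 58 list calls 57 remained with the block, and the unfolded protein response genes after Hyper-IL-6 were lost (adjusted p = 0.08). Of 207 values for named genes, 5 passed only with the block and 202 kept their side of the threshold. The Hyper-IL-6 arrays share only numbers with the others, since the deviations of 0 of 3 pairs with consecutive numbers correlated above 0.1 (r from −0.463 to −0.201).

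Socs3 after GFP-PFC, which passed in no line, changed sign in some settings. In the mean of 4 lines (0.01) it was −0.00184 with quantile normalization, −0.0235 with array weights and −0.0834 to 0.0974 with 1 array left out. With 1 array left out it was −0.00628 to 0.264 in CIR-1, −0.184 to 0.073 in CIR-2 and −0.237 to 0.486 in CIR-3. All other named genes kept their direction in every setting run. Of their 207 values, the calls of 58 ended with the compared groups alone, 45 with exon-level medians, 25 with every probe set, 12 with median centring, 8 with quantile normalization and 6 each with the trended prior and without the arrays numbered 1 and 2. With 3 arrays per group, simulated changes of 0.5 on the log2 scale were recovered for 68.7% to 76.1% of genes in the Hyper-IL-6 comparison, and smaller changes were not simulated. No background signal was used here, so dim genes could not be set against one.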

Other observations

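In this part, Plin2 was picked after its values were seen, and the tests between the arrays numbered 1 and 2 and the others rest on a grouping chosen after these arrays were seen to deviate together. Among 14 lipid loading genes, Plin2, which coats lipid droplets, rose after GFP-PFC in the mean of 4 lines by 0.31 (SE 0.062, adjusted p = 0.0211), with 0.28, 0.32, 0.35 and 0.31 in parental, CIR-1, CIR-2 and CIR-3 cells (SE 0.12 each). The list was not called (adjusted p = 0.418), and its median was −0.0275 and its mean 0.0194. Heat shock genes (adjusted p = 0.192), interferon-stimulated genes (adjusted p = 0.655) and unfolded protein response genes (adjusted p = 0.418, median 0.0068, mean −0.0053) were not called in this comparison, with 0 members passing in each. Oxidative stress genes had adjusted p = 0.0578, and 0.0152 with the block (adjusted p = 0.656 and 0.403 with an estimated correlation). Among quiescence and FOXO genes, 1 of 19 fell, Pik3ip1 by 0.16 (SE 0.033), a call that ended when 1 array was left out (list adjusted p = 0.258).

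Marker lists of other blood cell types were not called in the CIR lines for neutrophil and monocyte markers (adjusted p = 0.258, 0.814 and 0.423 in CIR-1, CIR-2 and CIR-3), B-lymphoid markers (0.99, 0.814 and 0.81) or T-cell markers (0.399, 0.814 and 0.16), nor were fibroblast markers (0.99, 0.814 and 0.31). Single members passed all the same. Besides Mpo, Lyz2, a lysozyme of myeloid cells, fell in CIR-3 by 0.79 (SE 0.093, adjusted p = 7.28e-06), and it differed by −0.24 in CIR-1 and 0.08 in CIR-2 without passing. Of genes chosen after their values were seen, the fibroblast list's S100a4 rose in CIR-2 by 1.10 (SE 0.13, adjusted p = 5.05e-06) and the B-lymphoid list's Cd72 rose in CIR-3 by 0.75 (SE 0.15, adjusted p = 0.00554), while the neutrophil granule gene Prtn3 differed by −0.05, 0.10 and 0.14 in the 3 lines and did not pass.

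The arrays numbered 1 and 2 stood apart from those numbered 3 to 6 in all 8 groups without Hyper-IL-6. Between these 24 arrays, grouped after seeing them, limma called 8119 of 19920 genes, 3254 higher and 4865 lower in numbers 1 and 2, of which 1 differed by 1 or more, Pim1 (−1.17, SE 0.15). Array brightness left in the deposited values was argued against, since the first component of the deviations held 43.3% of their variance after quantile normalization and 42.4% before. An effect of brightness or labelling from before the deposited normalization was not tested. Hyper-IL-6 signalling left over from the culture medium, in different amounts, may be a source, since the gp130/STAT3 early target list was lower in numbers 1 and 2 (adjusted p = 0.0238, mean −0.233), but with an estimated correlation its adjusted p was 0.614, so this and other differences between the numbers cannot be told apart here. The gp130 list was not alone, since oxidative stress genes (adjusted p = 0.00927), amino acid response genes (0.0153), STAT5 targets (0.0164) and ribosome biogenesis genes (0.0496) were also lower and G2/M genes higher in numbers 1 and 2 (1.9e-05), none of them called with an estimated correlation (adjusted p = 0.17 to 0.745).

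A hypothesis was that the constructs carry part of a mouse receptor gene, which would raise some exon-level probe sets of that gene in all 3 CIR lines. Of 27 receptor genes with exon-level values, 0 had at least 2 probe sets higher by 2 or more in all 3 lines, which argues against a part of these genes carried by all 3 constructs and covered by at least 2 probe sets. A part carried by 1 or 2 of the constructs was not tested. Among all genes, Sly had 10 such probe sets of 90, F5 had 6 of 27, Prkd3 had 4 of 20, and Tmbim7 and Tpst1 had 2 each.

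Other splits of the same arrays into groups of the same sizes were tested. In the mean of 4 lines, 3 of 100 splits within lines gave at least the 44 genes of the real split, the highest other 473, and among 100 splits that part all 12 pairs of consecutive numbers 1 did, the real one, the highest other giving 1. Among splits that keep the assumed pairs such a count was thus rare, which argues against chance without excluding it. The split with 473 points to a structure of the samples. For the 287 genes among the CIR lines, 1 of 100 splits gave as many, the real one, and the highest other gave 108. The drawn splits were not kept balanced over the replicate numbers, as the real one is, so chance was not excluded. For the difference of the GFP-PFC effect among lines (0 genes, 187 at an unadjusted p under 0.05 in limma), the highest other split gave 1, and 100 of 100 splits gave as many, which a count of 0 fixes in advance, so this says nothing about chance. The comparisons of 3 with 3 arrays have 10 splits, too few for a share under 0.05. Of these 10, as many genes as in the real split were given by 2 for Hyper-IL-6 (154, highest other 2618), 3 for CIR-1 (344, highest other 1027), 1 for CIR-2 (240, highest other 0), 2 for CIR-3 (297, highest other 1821) and 1 for Hyper-IL-6 against GFP-PFC (101, highest other 0). For GFP-PFC in single lines it was 10 each, which a count of 0 fixes in advance (highest other 578 in parental cells and 1 in each CIR line). The splits with 2618, 1027, 1821 and 578 genes point to a structure of the samples, and the counts with the replicate block are given above.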
